A study of Caenorhabditis elegans with 3 samples.

How the data were processed

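ChIP-seq of GFP-FLAG-tagged ELT-3 was run on whole L1 larvae of 1 transgenic strain, with sonicated chromatin per the labels. The 3 libraries formed 1 group. Biological replicate 1 had 1 library and biological replicate 2 had 2 technical libraries, which share an alignment per the deposited records of derived files and were counted as 1 replicate. No group served as a comparison, and the control experiment that the labels name was not analysed here.

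The peak lists came in the narrowPeak layout for the genome builds ce10 and ce11. The deposited records of derived files tie 1 list to each biological replicate, 1 list to the pooled alignments, and the IDR list to the pooled list and both replicate lists. Each peak has a signal value, deposited by the authors, whose scale differs between lists. Each peak also has a −log10 q-value, deposited by the authors, and a summit position. The aligner and the peak caller are not given in the sources used here. The lists hold no read counts, so sequencing depth is unknown, and the precision given is that of counts of peaks or genes. Signals were used within a list, except for rank correlations across overlapping peaks of different lists, given as a description. Results other than list sizes and chromosome shares rest on ce11 alone, which is the same assembly as WBcel235, and 0 peaks reached past a chromosome end there. Genes were taken from Ensembl annotation release 115, and coordinates are 1-based. No value was carried between builds.

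A gene was called bound when a summit lay from 1000 bp upstream to 200 bp downstream of its 5′ end. Summits were placed in promoter, exon, intron or intergenic sequence, in this order of precedence, and compared with 1000 sets of random positions on the same chromosomes. The motif WGATAR (A or T, GATA, A or G) was searched on both strands within 50 bp of each summit and in a window of equal size 500 bp to 1 randomly drawn side, and compared by a two-sided exact McNemar test, with an interval from 2000 bootstrap draws. The trend over signal quartiles was tested with 100000 permutations. Overlap of lists meant at least 1 shared bp and was compared with 1000 rotations of the peaks along their chromosomes. Windows of 20000 bp each side of elt-3 and unc-119 were compared with 10000 random windows of equal width on the same chromosome. Chromosome counts were tested with a two-sided exact binomial test. The 33 gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment at 0.05. Lists were written from textbook knowledge, and 1 collagen and 2 proteasome symbols without a match were left out. Proportions have exact 95% Clopper-Pearson intervals. The 25 mitochondrial peaks of replicate 2 were left out of comparisons.

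Genes were named by a rule: the 25 strongest IDR peaks with the gene of the nearest 5′ end, up to 4 bound members per list with the highest signal, and elt-3, unc-119 and the GATA factor genes whether bound or not. Genes named beyond it (vha-10, rpl-5, rps-12 and rps-19 as members of fixed lists, and mom-1 and ekl-5 as genes at named peaks) were chosen after their values were seen. The gene lists, this rule, the tests and most alternatives were fixed before the data were examined.

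Alternatives covered promoter windows, gene assignment, backgrounds, motifs, window sizes, stricter lists, overlap rules, locus widths, and the 1202 strongest peaks of either replicate alone in place of the IDR list. Others were added after the data were seen: the gene with the nearest 5′ end at any distance, peaks with or without WGATAR, peaks overlapped by replicate 2, non-coding genes, wider motif windows for replicate 2, and single replicates for the elt-3 window and the motif trend. The planned rotation of peaks for gene lists was changed after results were seen. Rotation in bp lowered the number of bound genes as a whole, which made lists with 0 bound members pass by construction. Bound and unbound genes were therefore rotated along the gene order of each chromosome, which keeps their number. With the planned 1000 rotations, a planted list that alone reached the smallest p had an adjusted p of 0.0659 in simulated data and was not called, so 10000 were used. In the real data 4 lists passed with either number.

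The motif comparison, the gene lists, the rotation along the gene order, the list overlap and the sequence words were tested on simulated data. The chromosome, location, elt-3 window, motif trend and non-coding gene comparisons were not. For the motif comparison, 359 of 359 planted sites in 1202 windows were found, and 4 of 100 null sets had p under 0.05. For the gene lists, 88 of 88 planted collagen genes were found and their list called, while 5 of 100 sets of random peaks gave any call over the 33 lists. The planted sites matched WGATAR and the planted peaks lay in the promoter window. Finding them was therefore given by construction, and checks the code but not the power to find real sites. For the rotation along the gene order, the planted list was called with 10000 rotations, and 1 of 40 null sets gave a call. These null sets were random genes without clusters, so the rate of false calls with clustered bound genes was not measured. For the overlap, 299 of 300 planted shared peaks were recovered as excess. For sequence words, the planted word ranked first of 2080. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.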

Results

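Binding of ELT-3 was mapped in whole first-stage (L1) larvae of Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced. ELT-3 is a GATA-type transcription factor known mainly from the epidermis, the tissue that secretes the cuticle. The worms came from a transgenic strain that carries ELT-3 fused to a GFP-FLAG tag together with an unc-119 rescue gene, and both sexes were pooled. The 3 libraries formed 1 group with 2 biological replicates. Replicate 2 consisted of 2 technical libraries with a joint alignment and was counted as 1 sample. The files were peak lists, which give no read counts, so the depth of each library is unknown. Peaks were called separately for replicate 1 (10775 peaks), for replicate 2 (4080 peaks) and on the pooled alignments (10082 peaks). The deposited records describe the replicate 2 and pooled lists as peaks and background. Their q-values are unlike: they ran to 0.960 in replicate 1, 0.961 in the pool and 0.00371 in replicate 2. Entries of these lists are called peaks here, but weak ones may be background. A list of 1202 peaks that had passed a filter on the irreproducible discovery rate (IDR), recorded as the optimal set, was taken as the main set. All of these were the 1202 strongest pooled peaks, and 1171 of them (97.4%) were among the 1202 strongest peaks of replicate 1, so the main set follows replicate 1 closely. Replicate 2 overlapped 117 of them (9.73%), so presence in the main set does not mean that a peak was called in both replicates. Peak signals are the authors' own values and were used to rank or filter peaks within a list, and between lists only in rank correlations given as a description. With 1 condition, peaks were compared with the genome and with other genes. The p-values describe these lists and not a population of replicates, and intervals cover counting error only.

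Most of the strongest peaks lay in promoter windows, those of several ribosomal protein genes among them. The highest peak, with a signal of 276.4 against a median of 48.0 for the IDR list, lay 278 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit (WBcel235 chromosome III, 3867492 to 3867666, promoter). The next promoter peak belonged to cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins (signal 204.0, II, 10563490 to 10563636). It was followed by iff-2, a homologue of the translation factor eIF5A (signal 174.5, II, 8561396 to 8561496), and by a peak shared by Y17G9B.5 and rpl-20 (signal 165.3, IV, 4750021 to 4750138). Promoters of rpl-15, rpl-35 and rpl-12, of the histone gene his-37 and of tasp-1 also carried peaks with signals between 140.9 and 159.8. Among the 25 strongest peaks, 20 lay in promoter windows, 3 in introns, 2 between genes and 0 in exons, and 5 had a ribosomal protein gene as the nearest gene. Further promoter peaks of this set lay at ska-3 (shared with rps-12), hsr-9 (shared with rps-19), rps-1, egg-5, serp-1.1, puf-9, wwp-1, imb-3, tag-340, wdr-23, a negative regulator of the stress factor SKN-1, and sec-61.G, a subunit of the translocon, whose signal of 119.6 was the lowest of the 25. The peaks outside promoters were in introns of let-607 (signal 143.0), of mom-1 (signal 142.5, nearest 5′ end cest-16) and of elt-3 (signal 131.6), and between genes near W02H3.3 (signal 185.4) and Y37A1A.2 (signal 133.3). Replicate 2 overlapped 3 of the 25 peaks, those near cdc-48.1, W02H3.3 and rpl-35.

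The fixed gene lists asked whether genes of the epidermis, of other cell types or of general cell functions carried promoter peaks more often than other protein-coding genes. In all, 688 of 19973 protein-coding genes had an IDR summit in the window from 1000 bp upstream to 200 bp downstream of the 5′ end. Ribosomal protein genes stood far above this level: 44 of 78 were bound (56.4%, 95% exact interval 44.7 to 67.6), against 3.24% of other genes. They comprised 27 of 47 large-subunit and 17 of 31 small-subunit genes, with a median signal of 60.9 and a median summit position of -292 bp from the 5′ end. After rpl-3, the strongest members were rpl-20, rpl-15 and rpl-35. The odds ratio was 38.7 (24.0 to 62.8), with an adjusted p of 1.77e-42 (two-sided Fisher's exact test, Benjamini-Hochberg over 33 lists). In the 1202 strongest peaks of replicate 2 alone, the number of bound ribosomal protein genes over the expected number fell from 17.4 to 2.47 (Fisher's exact test, adjusted p = 0.998). With only WGATAR peaks, a setting added later that holds fewer peaks, it was 6.07 (Fisher's exact test, adjusted p = 0.152). The other alternatives kept the call, with ratios down to 11.1, for the nearest gene at any distance. Their adjusted p ran from 1.79e-44 (Fisher's exact test) to 0.00330 (permutation tests with matched lists or rotation along the gene order).

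The vacuolar ATPase, the proton pump of lysosomes and of the apical epidermal membrane, was bound at 5 of 20 subunit genes, namely vha-1 (signal 82.6), vha-8 (signal 72.7), vha-12 (signal 70.9), vha-13 (signal 67.0) and vha-10. vha-10 had the lowest signal, 41.8. The odds ratio was 9.40 (2.67 to 27.3) and the adjusted p 0.00397. Heat shock protein genes were bound at 4 of 22, with an odds ratio of 6.26 (1.54 to 19.1) and an adjusted p of 0.0411. The bound members were the chaperone genes hsp-3 (signal 94.6), hsp-110 (79.4, a peak it shares with the proteasome gene rpn-3), hsp-60 (71.0) and hsp-1 (57.3), which act in the endoplasmic reticulum, cytosol and mitochondria. The heat shock call was lost in both other promoter windows (Fisher's exact test, adjusted p = 0.103 and 0.0941, range over all alternatives 0.00510 to 1). The vacuolar ATPase call was lost with the nearest gene at any distance, a setting added after the data were seen (permutation test, adjusted p = 0.0847, range over all alternatives 2.43e-05 to 1), and neither list had a bound member in the strongest peaks of replicate 2 alone. Proteasome subunits were bound at 3 of 30 genes (rpn-3, pbs-1 and pbs-3, Fisher's exact test, adjusted p = 0.382). Histone genes were bound at 3 of 72 (his-37, and his-67 and his-68 under a shared peak, Fisher's exact test, adjusted p = 0.938).

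Genes of the epidermis and its cuticle carried promoter peaks, with or without WGATAR, about as often as other genes. Over the 12 epidermal lists together, 15 of 399 genes had a promoter peak (3.76%), against 3.44% of other genes (odds ratio 1.1, 0.605 to 1.85, Fisher's exact p = 0.677). Cuticle collagens, the main structural proteins of the cuticle, were bound at 7 of 176 genes (odds ratio 1.16, 0.459 to 2.46, Fisher's exact test, adjusted p = 0.938). The strongest were col-38 (signal 72.0, a peak that also lies in the promoter of rpl-5), col-62 (66.5), col-147 (59.7) and col-159 (50.6, a peak shared with another bound collagen gene). Single epidermal genes with a peak included pdi-2 and dpy-31, which process collagen, and nhr-25, a nuclear receptor needed for molting. Others were the antimicrobial peptide genes nlp-31 and nlp-34 under 1 shared peak (signal 94.3), osm-11 of the osmotic response, grl-11 and sma-10. The sma-10 peak also lies in the promoter window of the chemoreceptor gene srh-282, and the grl-11 summit lies nearer the 5′ end of another gene. No epidermal list reached an adjusted p under 0.05, and 0 reached an unadjusted p under 0.05. The smallest unadjusted value was 0.0926, for collagen processing enzymes. Furrow collagens, cuticlins, patched-related genes and epidermal junction genes had 0 bound members.

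Chemoreceptor, C-type lectin and F-box genes were bound less often than other genes. Chemoreceptor genes, which act in sensory neurons, were bound at 4 of 1269 (srh-17, srh-282, str-7 and srh-2), with an odds ratio of 0.0833 (0.0226 to 0.215, Fisher's exact test, adjusted p = 7.11e-14). Of 240 C-type lectin genes 0 were bound (Fisher's exact test, adjusted p = 0.00397). F-box genes were bound at 3 of 322 (fbxc-19, fbxb-96 and fbxa-83, odds ratio 0.260, 0.0533 to 0.771, Fisher's exact test, adjusted p = 0.0439). The lectin call was lost in the stronger-signal part of the list (Fisher's exact test, adjusted p = 0.164, range over all alternatives 9.80e-05 to 1), and the F-box call when bound and unbound genes were rotated along the gene order (permutation test, adjusted p = 0.147, range over all alternatives 0.0162 to 1). In the strongest peaks of replicate 2 alone, F-box genes had 1.19 times the number of bound genes that chance gives and none of the 3 families passed the test. Markers of intestine, body wall muscle, pharynx and neurons had 0 bound members, and germline markers had 1 of 29 (cgh-1). Over these 5 lists together the count was 1 of 142 (Fisher's exact p = 0.0986). Nuclear hormone receptors were bound at 10 of 269 genes, led by nhr-80 (signal 112.1), nhr-68 (87.3), nhr-119 (80.8) and nhr-35 (60.1), with an adjusted p of 0.938. Glutathione S-transferases were bound at 3 of 44 genes (gst-42, gst-27 and gst-20), UDP-glucuronosyltransferases at 4 of 67 (ugt-19, ugt-58, ugt-39 and ugt-20) and cytochrome P450 genes at 2 of 74 (cyp-29A4 and cyp-34A9). Homeobox genes were bound at 2 of 86 (ceh-38 and ceh-20), innexins at 2 of 24 (inx-13 and inx-12) and astacin proteases at 0 of 37. None of these remaining families passed the test.

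**Figure D1:**
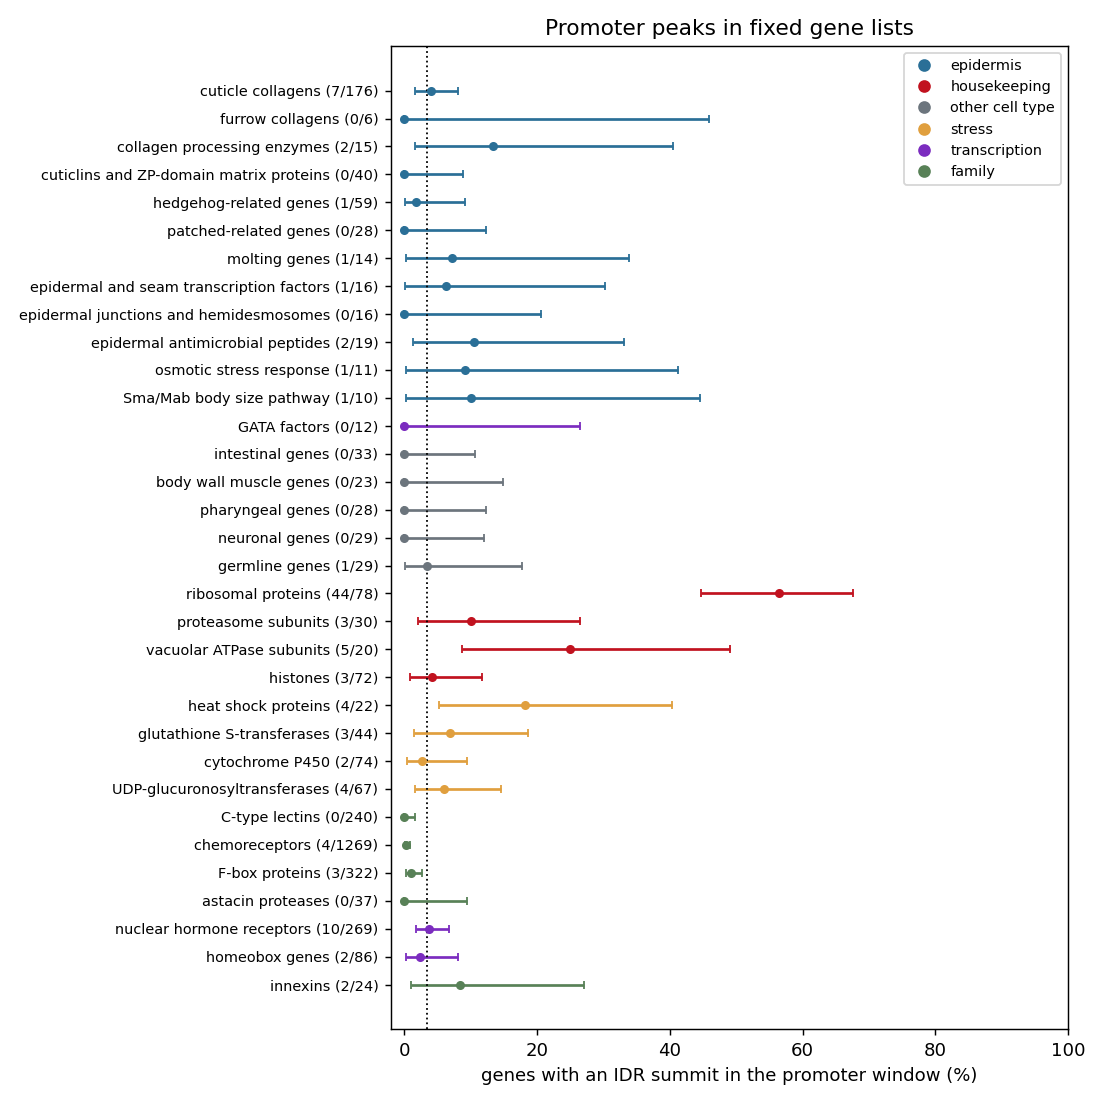
Percent of the genes of each fixed list with an IDR summit in the promoter window, with 95% exact binomial intervals, bound and listed genes in parentheses and colours for the class of list. The dotted line marks all protein-coding genes; ribosomal proteins, with 44 of 78 genes, stand apart to the right.

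Several peaks lay within and around elt-3 itself, the gene that this strain also carries as a tagged transgene. Between 20000 bp upstream and 20000 bp downstream of elt-3 (WBcel235 X, 13934874 to 13941216, plus strand) the IDR list held 7 peaks, or 1.51 per 10 kb. Of these, 4 lay in introns of elt-3, the strongest at X, 13937398 to 13937693, with a signal of 131.6 and 2 matches to the GATA motif WGATAR. Another 3 lay upstream of elt-3. Those at -2263 and -14311 bp from its 5′ end, with signals of 36.6 and 111.0, were between genes, and the one at -17367 bp, with a signal of 41.2, was in the promoter window of ekl-5, at -336 bp. Random windows of the same width on X held a mean of 0.674 peaks, and 99.7% of 10000 windows held fewer than 7 (fold 10.4). The pooled list held 25 peaks there, more than the highest random window (24). Replicate 2 held 1 peak there, against a median of 2, so the excess rests on replicate 1. Around unc-119, the other gene of the transgene, the IDR list held 0 peaks against a random mean of 0.637.

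Of the 12 GATA factor genes, 0 had a promoter peak. egl-27, a related gene with a GATA-type zinc finger, had 2 peaks within the gene, the nearer 7845 bp from its 5′ end (signal 77.6). The epidermal factors elt-1, egl-18 and elt-6 and the endodermal factors elt-2, elt-4, elt-7, end-1, end-3, med-1 and med-2 had none in the gene. The nearest summit to med-1 was at -5040 bp and that to med-2 at 10824 bp, and for unc-119 the nearest was 86986 bp away.

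**Figure D2:**
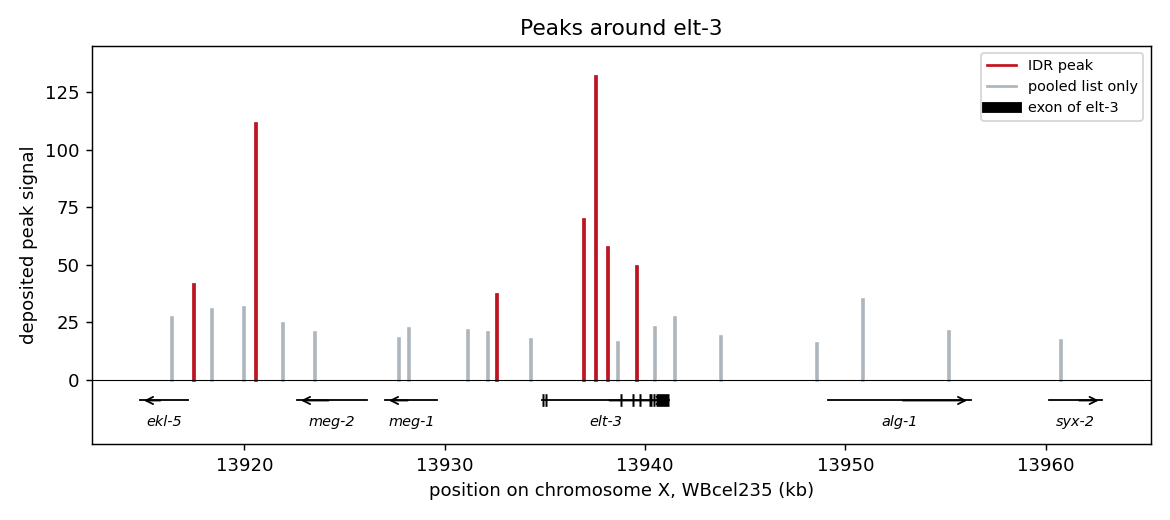
Position on chromosome X (kb, WBcel235) of the peaks around elt-3 against their deposited signal, with 7 IDR peaks in red, peaks of the pooled list only in grey, and genes below as arrows with the exons of elt-3 as blocks. The tallest IDR peak, with a signal of 131.6, lies in an elt-3 intron.

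The sequence that GATA factors bind was enriched at the summits. WGATAR occurred within 50 bp of 468 of 1202 IDR summits (38.9%, 95% exact interval 36.2 to 41.8) and in 226 windows placed 500 bp away (18.8%). The difference was 20.1 percentage points (bootstrap interval 16.6 to 23.4). The motif was at the summit only in 372 peaks and in the flank only in 130 (two-sided exact McNemar test, p = 4.74e-28). The 500 strongest peaks of replicate 1 gave 39.4% against 21.2% (exact McNemar p = 2.51e-10). Nuclear peaks of replicate 2 gave 22.2% against 21.8% (exact McNemar p = 0.647), and its 500 strongest gave 24.4% against 22.8%, a difference of 1.60 percentage points (-3.80 to 6.60, p = 0.591). With the 1202 strongest peaks of replicate 2 in place of the IDR list the difference was 0.666 percentage points (exact McNemar p = 0.734). Replicate 2 peaks are wider than the 50 bp windows. Searched over whole replicate 2 peaks, with flanks 1000 bp away, the difference was 1.33 percentage points (exact McNemar p = 0.162). That setting was added after the data were seen.

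**Figure D3:**
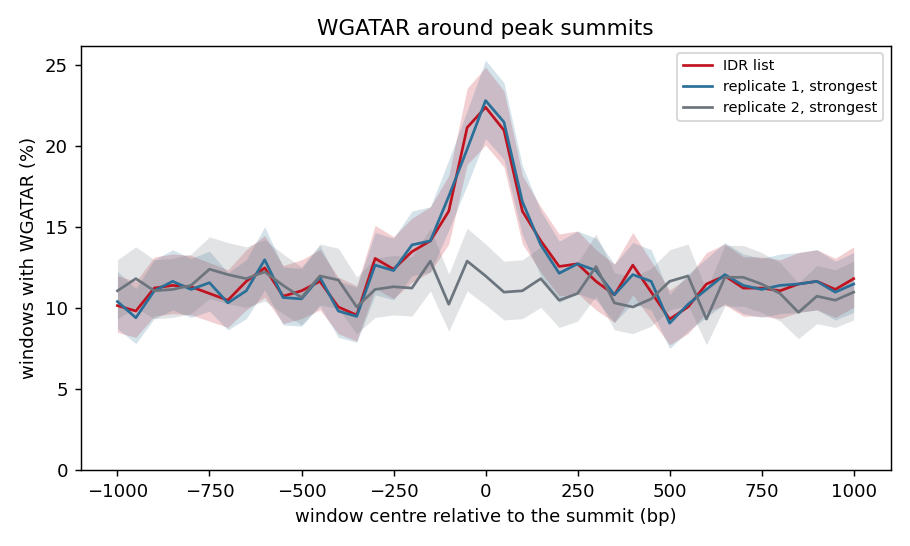
Percent of windows with WGATAR against the distance of the window centre from the summit (bp), for the IDR list and the strongest peaks of each replicate, with 95% exact binomial intervals as bands. The IDR and replicate 1 lines peak at the summit, and the replicate 2 line shows no such peak.

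The motif was no more frequent at peaks with a high signal. Its share was 38.0%, 38.2%, 43.2% and 36.3% from the lowest to the highest signal quartile, a fitted trend of 0 percentage points per quartile (two-sided permutation p = 1). Across peaks, which are not independent replicates, Spearman's rho between signal and number of matches was 0.0135 (permutation p = 0.643). Among the 25 strongest peaks 3 had a match, those at mom-1, Y37A1A.2 and elt-3, and among the 10 strongest, which include rpl-3, cdc-48.1 and iff-2, 0 had one. Of the 41 peaks in ribosomal protein promoters 4 had a match (9.76%), against 146 of 489 other promoter peaks (29.9%, odds ratio 0.254, Fisher's exact p = 0.00596).

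Promoter windows held more summits than random positions gave, counting peaks with and without WGATAR together. Promoter windows held 530 summits (44.1%, 95% exact interval 41.3 to 47), against 21.1% of random positions on the same chromosomes (fold 2.09). Introns held 276 summits (23%, fold 0.747), intergenic sequence 353 (29.4%, fold 1.17) and exons 43 (3.58%, fold 0.155). Each of these shares gave a two-sided permutation p of 0.002, the smallest that 1000 random sets allow. The median summit lay at -180 bp from the nearest 5′ end, and 398 summits (33.1%) lay within 500 bp upstream of one. In replicate 2 the promoter share was 25.2% (fold 1.18). WGATAR was less frequent at promoter peaks than in the IDR list as a whole. It was found at 4 of 41 ribosomal protein promoter peaks and 146 of 489 other promoter peaks (29.9%), against 38.9% of all IDR summits. The location of WGATAR peaks alone was not tested, so the promoter excess does not describe them.

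The X chromosome, which worms carry in different copy number in each sex, held 263 peaks (21.9%, 95% exact interval 19.6 to 24.3). This was 1.24 times its share of the genome (two-sided exact binomial test, adjusted p = 0.000619 over 6 chromosomes). The strongest replicate 2 peaks, in place of the IDR list, gave a similar fold of 1.25 on X (exact binomial test, unadjusted p = 0.000112). Those peaks showed no clear WGATAR enrichment, so the excess on X was not particular to a list enriched for GATA sites. Chromosome III held 191 (fold 1.16, exact binomial test, adjusted p = 0.0490). Chromosomes V and IV held fewer peaks than their length gives, with 192 (fold 0.765, exact binomial test, adjusted p = 0.000119) and 176 (fold 0.839, adjusted p = 0.0195). With shares of protein-coding genes as the expectation, chromosome IV did not pass (fold 0.891, exact binomial test, adjusted p = 0.102). Chromosomes I and II did not pass the exact test (adjusted p = 0.271 and 0.936).

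The replicates were compared by the overlap of their peaks. Replicate 2 peaks were all 596 bp wide, and its nuclear peaks had a median signal of 2.65, on a scale of its own. Of the 10775 replicate 1 peaks, 590 (5.48%, 95% exact interval 5.05 to 5.92) overlapped a nuclear replicate 2 peak by at least 1 bp, against a mean of 361 and a highest count of 428 under rotation along the chromosomes (fold 1.64). Between the 500 strongest peaks of each list, 15 overlapped, against a mean of 2.10 (fold 7.14). Of the IDR peaks, 117 (9.73%) overlapped replicate 2, against a mean of 40.2. Each comparison gave a two-sided permutation p of 0.002, the smallest that 1000 rotations allow. Across overlapping peaks, as a description, Spearman's rho of signal was 0.99 between the IDR list and replicate 1, 0.143 between the IDR list and replicate 2, and -0.0210 between the replicates.

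**Figure D4:**
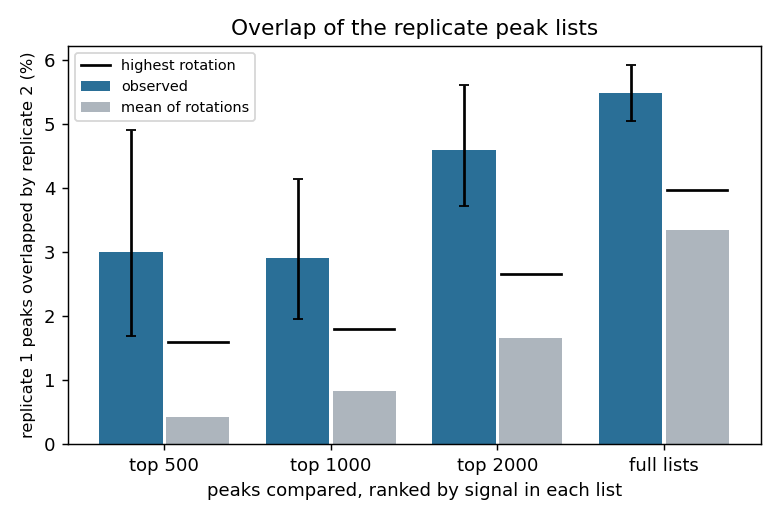
Percent of replicate 1 peaks overlapped by replicate 2 for the strongest peaks of each list and the full lists, with 95% exact binomial intervals, beside the mean of 1000 rotations in grey and the highest rotation as a line. The observed share lies above the highest rotation in each of the 4 comparisons.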

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

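The test of WGATAR at ribosomal protein peaks, the count of replicate 2 peaks around elt-3, the gene list settings by motif or replicate 2 overlap, and the overlap of replicate 2 with IDR peaks split by WGATAR were chosen only after results were seen. The design has 1 group, so no biological difference between groups was tested; tests of binding with or without a GATA site concern sequence at the peaks alone.

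Mitochondrial DNA held 25 of the 4080 replicate 2 peaks, a signal outside the nuclear comparisons and above the 3 that a count of 0 allows. Their signals ran from 2.02 to 34.8 with a median of 10.47. Nuclear peaks of replicate 2 had a median of 2.65 and a highest signal of 10.52, so its strongest peak was mitochondrial. The IDR, pooled and replicate 1 lists held 0 such peaks.

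The replicate 2 list showed little sign of the GATA motif; its length cannot be set against that of the replicate 1 list, which ran to a q-value of 0.960 where replicate 2 stopped at 0.00371. Weaker enrichment at the same sites may contribute: replicate 2 overlapped 11.6% of the 500 strongest replicate 1 peaks (8.93 to 14.7), above the highest rotation (6.20%). Whether replicate 2 lacked ELT-3 enrichment, as input-like or mislabelled libraries would, cannot be told apart from this: the motif test at its 500 strongest summits gave an exact McNemar p of 0.591, while it overlapped 8.12% of IDR peaks with WGATAR (highest rotation 6.41%) and 10.8% of those without (highest rotation 5.45%). IDR peaks that replicate 2 overlapped had WGATAR with an odds ratio of 0.733 against the others (0.475 to 1.12, Fisher's exact p = 0.136), which leaves open whether the shared peaks are GATA sites. Open chromatin recovered in any library would also give shared peaks.

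Ribosomal protein genes carried promoter peaks more often than other genes, as did the 4 housekeeping lists as a class (55 of 200 genes, Fisher's exact p = 3.14e-34). The class value is carried by the ribosomal proteins, which gave 44 of the 55 bound genes, and proteasome subunits and histones did not pass on their own. The values argue against promoter GC content, since 44 ribosomal protein genes were bound against a highest count of 13 in 10000 lists matched on it. That match used GC content of promoters (37.1% for ribosomal protein genes, 35.2% for others). It does not cover GC content near the summits, 44.9% for the IDR list against 35.6% in flanks. The values also argue against a GATA site at the summit, since WGATAR had an odds ratio of 0.254 at ribosomal protein peaks against other promoter peaks. Binding at active promoters without a GATA site at the summit may account for peaks of the housekeeping lists: 5 of 50 had WGATAR, against 7 of 12 at epidermal genes (odds ratio 0.0847, Fisher's exact p = 0.000832). Promoter activity was not measured. The 50 peaks are mostly ribosomal protein promoter peaks, of which 4 of 41 had WGATAR, so the comparison largely repeats the one for ribosomal protein promoters. Recovery of such promoters in any library cannot be told apart from ELT-3 binding, since replicate 2 peaks were more frequent in ribosomal protein promoters (odds ratio 3.28, 1.61 to 6.14), as that cause predicts, while the odds ratio lay below the 38.7 of the IDR list, which had been set beforehand as a result against it. That bound may have been poorly set, because replicate 2 overlapped only 117 of the 1202 IDR peaks. Whether and how far few shared peaks lower such an odds ratio was not measured.

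The window around elt-3 held 7 IDR peaks, above the 95th percentile of 2 in random windows on X, and the excess was 21.1-fold within 5 kb and 5.80-fold within 50 kb. Extra copies of the transgene DNA may raise the signal over the whole insert, as the count of 7 allows. Binding of ELT-3 at its own gene could also give peaks there, but how many was not tested, so the count cannot separate these causes. The IDR peaks upstream of elt-3 had 0 matches to WGATAR each, and those in its introns had 1, 2, 0 and 1. Copies present in every library without immunoprecipitation would put the replicate 2 count above the 95th percentile of random windows. Replicate 2 had 1 peak there, below the median of 2, which had been set as a result against that cause. So low a count decides little, since its exact Poisson upper limit of 5.57 lies above the 95th percentile of 5. Such copies therefore cannot be told apart from the other causes named. The 0 IDR peaks around unc-119 belong to the other gene of the transgene, whose copied extent is not given in the sources used here.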

How the results depend on the processing

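The settings by motif, by overlap with replicate 2, by nearest gene at any distance, by rotation along the gene order, and single replicates for the elt-3 window and the motif trend were chosen after results were seen. Of 134 alternative values, 98 kept the direction and side of the threshold of the reported value (counts: within 1.5 times), 24 kept the direction and lost the call, 3 counts moved and 9 reversed. Of these 134, 88 were planned, with 73, 11, 1 and 3. The 98 are no measure of robustness. The replicate 1 list shares 1171 peaks with the main set, and the collagen and motif trend values had no call to lose. Another value put non-coding genes in place of promoters, which is a different quantity. The share on X, promoter excess and replicate overlap kept their calls in every setting run. For X these settings include the strongest replicate 2 peaks alone (fold 1.25), so the kept call does not tie that excess to GATA sites. Chromosome IV lost its call with shares of genes as the expectation (fold 0.891, exact binomial test, adjusted p = 0.102). Using only the strongest peaks of 1 replicate, the motif difference ran from 0.666 (replicate 2) to 17.3 percentage points (replicate 1), lists passing from 0 to 6, and the elt-3 fold from 0 to 10.6. Bound over expected ran from 2.47 to 17.4 for ribosomal proteins, 0 to 7.28 for vacuolar ATPase, 0 to 5.29 for heat shock proteins, 0.119 to 0.796 for lectins, 0.0859 to 0.537 for chemoreceptors and 0.266 to 1.19 for F-box proteins. Only with WGATAR peaks, 0 lists passed: the ratios were 6.07 for ribosomal proteins, 0 for vacuolar ATPase, heat shock and lectins, 0.351 for chemoreceptors and 0.357 for F-box proteins (0.237 without WGATAR). With peaks overlapped by replicate 2, 1 list passed, the ribosomal proteins (ratio 38.5), a pass built in because the subset comes from a list already enriched for them, and the difference from 17.4 was not tested. The other ratios were 0 for collagens, vacuolar ATPase, heat shock, lectins and F-box proteins and 0.246 for chemoreceptors. These subsets hold fewer peaks, which alone lowers the power. For heat shock proteins the ratio was 5.25 and 3.76 in the narrower and wider window, 3.44 for the nearest gene, 4.69 against matched lists, 5.36 under rotation and 3.78 for the nearest gene at any distance, all without a call. It kept its call at 10.05 in the stronger list and 7.07 without WGATAR, and vacuolar ATPase at 11.1 and 9.74. For F-box proteins it was 0.231 for the nearest gene, 0.276 under rotation, 0.506 in the stronger list and 0.324 at any distance, and it kept its call at 0.117 and 0.317 in the narrower and wider window. It was 5.02 for vacuolar ATPase at any distance and 0 for lectins in the stronger list, both without a call. The cause was not tested. The planned rotation of peaks in bp was void for gene lists, since it let lists with 0 bound members pass by construction. A planned overlap of at least 50% of both peaks gave no value: replicate 1 peaks are at most 296 bp wide, less than 50% of the 596 bp of each replicate 2 peak. Unknown depth limits all comparisons between lists.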

Other observations

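The tests of non-coding genes, of nearest genes at any distance and of sequence words were chosen only after results were seen.

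Genes of small nucleolar, small nuclear and transfer RNAs carried more IDR summits than rotated peaks gave. Within 100 bp of small nucleolar RNA genes, which guide modification of ribosomal RNA, lay 33 summits against a rotation mean of 1.45 (fold 22.7). Small nuclear RNA genes of the spliceosome had 11 against 0.466 (fold 23.6) and transfer RNA genes 19 against 2.13 (fold 8.91). The excess was not particular to them: the general class of non-coding RNA genes had 154 against 29.3 (fold 5.25), and all non-coding genes without pseudogenes 210 against 58.8 (fold 3.57). Pseudogenes had 0 summits against a mean of 40.3. Each of these had an adjusted p of 0.00366 (two-sided permutation test, Benjamini-Hochberg over 11 classes), resting on the smallest p the rotations give. Other small RNA classes did not share the excess: piRNA genes had fewer summits, 11 against 22.7 (adjusted p = 0.0345), and microRNA genes had 1 against 0.898 (permutation test, adjusted p = 1). In replicate 2, which has its own peak width, small nucleolar RNA genes had 5 summits against 4.59, and none of the 11 classes passed. Small nucleolar RNA genes in C. elegans often lie within other genes, ribosomal protein genes included, and the counts were not separated by host gene.

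Nuclear hormone receptors came out above the rotations when each summit was given to the gene of the nearest 5′ end at any distance. In all, 30 receptor genes were nearest to a summit against a mean of 13.5 and a highest count of 28 in 10000 rotations (fold 2.22, permutation test, adjusted p = 0.00165), although promoter peaks alone gave no such excess (adjusted p = 0.938). Ribosomal proteins (25 genes, fold 11.1), chemoreceptors (8 genes, fold 0.186) and C-type lectins (0 genes) also passed. Cuticle collagens did not, with 11 genes (fold 1.37, permutation test, adjusted p = 0.559), and no other epidermal list did. Their folds were unlike, on few genes each. Antimicrobial peptides had 3.95, Sma/Mab genes 3.75, collagen processing enzymes 3.68, epidermal transcription factors 3.05 and molting genes 3.02. Osmotic response genes had 2.22 and junction genes 1.39. Patched-related genes had 0.404, cuticlins 0.336, and furrow collagens and hedgehog-related genes 0. The lowest adjusted p of these lists was 0.123 (permutation test).

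Sequence words other than GATA sites were frequent at the summits. GAGAGA occurred within 50 bp of 27.1% of IDR summits and in 5.66% of flanks (exact McNemar test, adjusted p = 6.06e-44 over 2080 words). ACGCAG occurred at 14.6% against 1.83%, and CTTATC, the reverse complement of a GATA site, at 16.7% against 3.0%. In all, 491 words were more and 361 less frequent at the summits, where GC content was 44.9% against 35.6% in flanks, so base composition enters these counts. GAGAGA was found at 25.4% of peaks with WGATAR and 28.2% of those without (Fisher's exact p = 0.318), and at 9.76% of ribosomal protein promoter peaks against 27.7% of the others (p = 0.0111). At the 1202 strongest replicate 2 summits 0 words differed, and GC content was 35.5% against 35.4%.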
